A study of Mus musculus with 8 samples.

How the data were processed

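RNA was extracted from sorted CD11b+Gr1+ splenocytes of the CD38high and CD38low fractions, amplified by T7 transcription, converted to cDNA, biotin-labelled and hybridised to Affymetrix GeneChip arrays, per the labels' protocols. The authors deposited a table of log2 expression values, with 1 row per probeset and 1 column per array, and a second table of the probesets they listed as changed. Per the submitters' processing notes, the Affymetrix Power Tools, RMA and PLIER were used, with the mouse build mm9. Which of RMA and PLIER gave the deposited values, the annotation used and any filter on probesets are not given in the sources used here. That the values are on a log2 scale was read from their range, from 3.60 to 14.10, and from the difference column of the authors' deposited table, which lay within 0.0005 of the difference of the group means in all 498 probesets although its header reads as a ratio. Scanner files and scan dates were not used here, so background correction and batches could not be examined. The deposited normalization was kept.

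The value table pairs no probeset with a gene. Each of the 498 rows of the authors' deposited table equalled exactly 1 of the 23332 rows of the value table in all 8 values, compared to 5 decimals, and this match gave 484 probesets a gene name (2.07% of all), for 482 genes. The other 14 matched rows and all other probesets have no name here. Symbols were updated through the RefSeq transcript accession (476 rows), the symbol (3 rows) or a synonym (4 rows) in a table of the GRCm38.p6 annotation, used for names only, and 1 name was kept as in the file. Chromosomes are those of the authors' table. All named genes thus come from a list the authors chose on these arrays.

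Groups were taken from the sample titles. In the main analysis, fixed before the data were examined, CD38high and CD38low arrays (4 each) were compared without a block, since the series design names an unpaired test, with lmFit and eBayes of limma 3.58.1 in R 4.3.3. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all 23332 probesets and called under 0.05. Differences are CD38high minus CD38low on the log2 scale, and folds are 2 to that power. SE is the moderated standard error of limma. Both fractions of a mouse came from the same animal, and both fractions of the pool from splenocytes pooled before sorting, per the labels and the series design. Deviations from the group means correlated at 0.345 to 0.675 between the 2 arrays of a mouse or pool and at -0.577 to 0.1 between other arrays of opposite groups, so mouse or pool as a replicate block is given as the paired fit. No p-value here covers differences between further batches of mice.

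The text names Cd38, the 12 named genes with the largest difference in each direction (adjusted p under 0.05, the same direction in all 4 pairs, no predicted genes, small RNAs or immunoglobulin segments, which left out 1 gene), and in each gene list up to 4 members with the largest difference. A gene with several probesets is represented by the one with the highest mean, and both are in the same direction for the 2 genes concerned, Ankrd33b and Wdr36. The 30 gene lists, of which 11 hold markers of other cell types, were also fixed beforehand. The planned background of all genes could not be used, since the remaining probesets have no names, and the planned rotation test (fry) was not run, since genes selected for change fix its outcome. The 4 lists with at least 5 named genes were therefore tested with camera (preset correlation 0.01) against the other named genes, 120 higher and 362 lower, with Benjamini-Hochberg adjustment over the 4 lists, and Fisher's exact test of direction was added after the names were known. A further 16 lists have 1 to 4 named genes and 10 have none.

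Alternatives were the replicate block, fixed or random, leaving out each pair or array, quantile or median scaling on top, filters on dim probesets, trended robust eBayes, array weights, the methods' t-test (equal variance, without the 10000 permutations that the series design names), only named probesets, means of probesets of a gene and an estimated correlation in camera. Simulated arrays were built from the means, residual spread and averaged pair deviations of these probesets, with 200 changed ones among 23332. There the unpaired fit recovered 64% of 2-fold and 93% of 4-fold changes with 3 false calls. The paired fit recovered 72% and 97% with 11 false calls. The simulated share of changed probesets was below the share called in the real arrays (10.6%), so these rates need not hold there. The averaged pair deviations also hold residual noise, to which noise at the full residual SD was added, independently for each probeset. This widened the spread in the unpaired fit, so the rates do not rank the 2 fits. Other calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.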

Results

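Gene expression was measured on 1-channel Affymetrix GeneChip arrays in splenocytes that carry both CD11b and Gr1, the surface phenotype used for mouse myeloid-derived suppressor cells. The cells came from 12-month-old L2-Cre;p120f/f mice with esophageal tumors. In this line a Cre transgene acts on a floxed p120 gene. From each spleen preparation the cells were sorted into a CD38high and a CD38low fraction. CD38 is a surface enzyme that consumes NAD. There were 8 arrays in all, 4 per fraction, and each fraction was represented by 3 individual mice (mice 1, 2 and 3) and by 1 pool of splenocytes from 3 mice. The pool counted as the fourth replicate, and the labels do not say whether its mice were others than mice 1 to 3. The 2 fractions of a mouse or of the pool form a pair. Each array had values for 23332 probesets on the log2 scale, with medians between 6.92 and 7.10, and precision was limited by the number of arrays. Across all probesets, arrays of the same fraction correlated at 0.959 to 0.988, the 2 arrays of a mouse or the pool at 0.969 to 0.979, and the remaining array pairs at 0.935 to 0.976; these are correlations across probesets, which are not independent replicates.

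The comparison asked which transcripts differ between the CD38high and the CD38low fraction of these myeloid cells. The Cd38 transcript (chromosome 5) followed the sort. It stood at 12.46 ± 0.15 (SD, n = 4) in CD38high and at 10.46 ± 0.57 (SD, n = 4) in CD38low cells, a log2 difference of 2.00 ± 0.26 (SE, limma adjusted p = 0.00375). It was higher in 4 of 4 pairs. Since the cells were sorted on the CD38 protein, this checks the labels and is no independent result. Rows for the other sort antigens, Itgam, Ly6g, Ly6c1 and Ly6c2, could not be located by name and were not analysed here.

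In the unpaired limma fit 2479 probesets, 10.6% of all, differed at an adjusted p under 0.05. Of these, 873 were higher and 1606 were lower in CD38high cells. With at least a 2-fold difference there were 188 higher and 450 lower. With the mouse or pool as a replicate block the paired fit called 3929 probesets, 1626 higher and 2303 lower, of which 273 and 474 differed at least 2-fold. The direction was the same in all 4 pairs for 2475 of the 2479 probesets, which a call with 4 arrays per group largely fixes. The unpaired count fell to 540, 1334 and 1125 without both arrays of mouse 1, mouse 3 or the pool, and to 1188, 1460 and 1591 without the CD38high array of mouse 1, the CD38high array of the pool or the CD38low array of mouse 1. The count of higher probesets fell to 551 without the CD38low array of mouse 3. The paired fit called 1942, 2520, 2419 and 2317 probesets without mouse 1, mouse 2, mouse 3 or the pool.

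**Figure D1:**
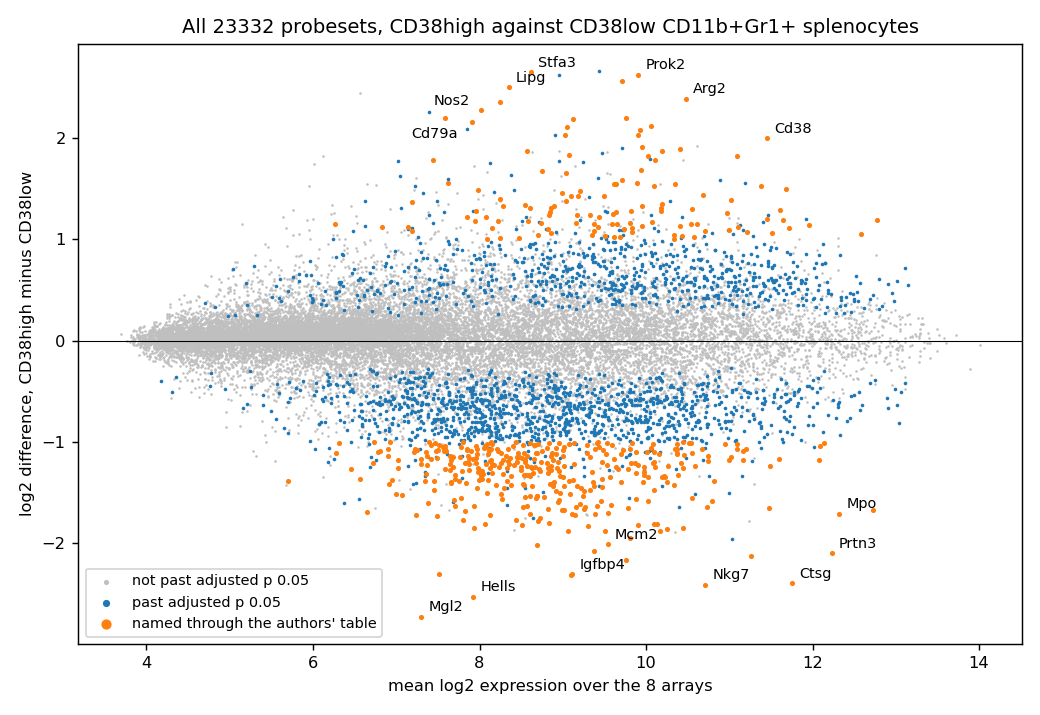
Log2 difference between CD38high and CD38low cells (vertical axis) against the mean log2 expression over the 8 arrays (horizontal axis), with 1 point per probeset. Blue points passed an adjusted p of 0.05 in the unpaired limma fit, grey points did not, and orange points could be named through the authors' deposited table; 1606 of the 2479 called probesets lie below 0.

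The named genes with the largest differences towards CD38high cells came from several functional classes. Stfa3, a stefin A inhibitor of cysteine proteases (chromosome 16), was 6.26-fold higher, at 9.94 ± 0.15 against 7.30 ± 0.59 (SD, n = 4 each; log2 difference 2.65 ± 0.27 SE, limma adjusted p = 0.00154). Prok2, a secreted prokineticin (chromosome 6), was 6.16-fold higher (2.62 ± 0.49 SE, limma adjusted p = 0.0146). A pair of enzymes that use arginine was among them. Arg2, the mitochondrial arginase (chromosome 12), stood at 11.67 ± 0.26 against 9.28 ± 0.98 (SD, n = 4 each), a 5.23-fold difference (limma adjusted p = 0.0139). Nos2, the inducible nitric oxide synthase (chromosome 11), stood at 9.15 ± 0.62 against 6.88 ± 0.26 (SD, n = 4 each), a 4.84-fold difference (limma adjusted p = 0.00367). Ggt1, which cleaves glutathione outside the cell (chromosome 10), was 5.92-fold higher. Lipg, endothelial lipase (chromosome 18), was 5.65-fold higher. St3gal6, a sialyltransferase (chromosome 16), was 5.11-fold higher. Adam19, a membrane metalloprotease (chromosome 11), was 4.60-fold and Timp2, an inhibitor of metalloproteases (chromosome 11), was 4.22-fold higher. Chil5, a chitinase-like gene listed in the files as Bclp2 (chromosome 3), was 4.32-fold and Aqp9, a water and glycerol channel (chromosome 9), was 4.30-fold higher. Cd79a, a part of the B cell receptor complex (chromosome 7), was 4.46-fold higher, at 8.99 ± 0.75 against 6.84 ± 0.37 (SD, n = 4 each; limma adjusted p = 0.00993). Adjusted p for these 12 genes lay between 0.000684 and 0.0146 in the unpaired fit. Stfa3 and Chil5 belong to families of closely similar genes whose probes may not separate them.

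Among the named genes lower in CD38high cells, the largest difference was that of Mgl2, a galactose-binding lectin of macrophages and dendritic cells (chromosome 11). It was 6.60-fold lower, at 5.94 ± 0.33 against 8.66 ± 0.31 (SD, n = 4 each; log2 difference -2.72 ± 0.20 SE, limma adjusted p = 0.000684). Hells, a helicase of proliferating cells that acts on chromatin (chromosome 19), was 5.76-fold lower, at 6.66 ± 0.10 against 9.19 ± 0.37 (SD, n = 4 each; limma adjusted p = 0.000609). Ctsg, Prtn3 and Ms4a3, genes of early granulocyte precursors, were lower by 5.26-fold, 4.29-fold and 4.38-fold. Nkg7, a granule membrane protein of cytotoxic cells (chromosome 7), was 5.31-fold lower. Clec4b2, a C-type lectin receptor, was 4.97-fold lower. Igfbp4, which binds insulin-like growth factors, was 4.95-fold lower. Gria3, a glutamate receptor subunit, was 4.93-fold lower. Tfec, a transcription factor of the MITF family that the files list as Tcfec, was 4.50-fold lower. Tnfsf13, the cytokine APRIL, was 4.22-fold and Pole2, a subunit of DNA polymerase epsilon, was 4.04-fold lower. Adjusted p for these 12 genes lay between 0.000307 and 0.00963.

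**Figure D2:**
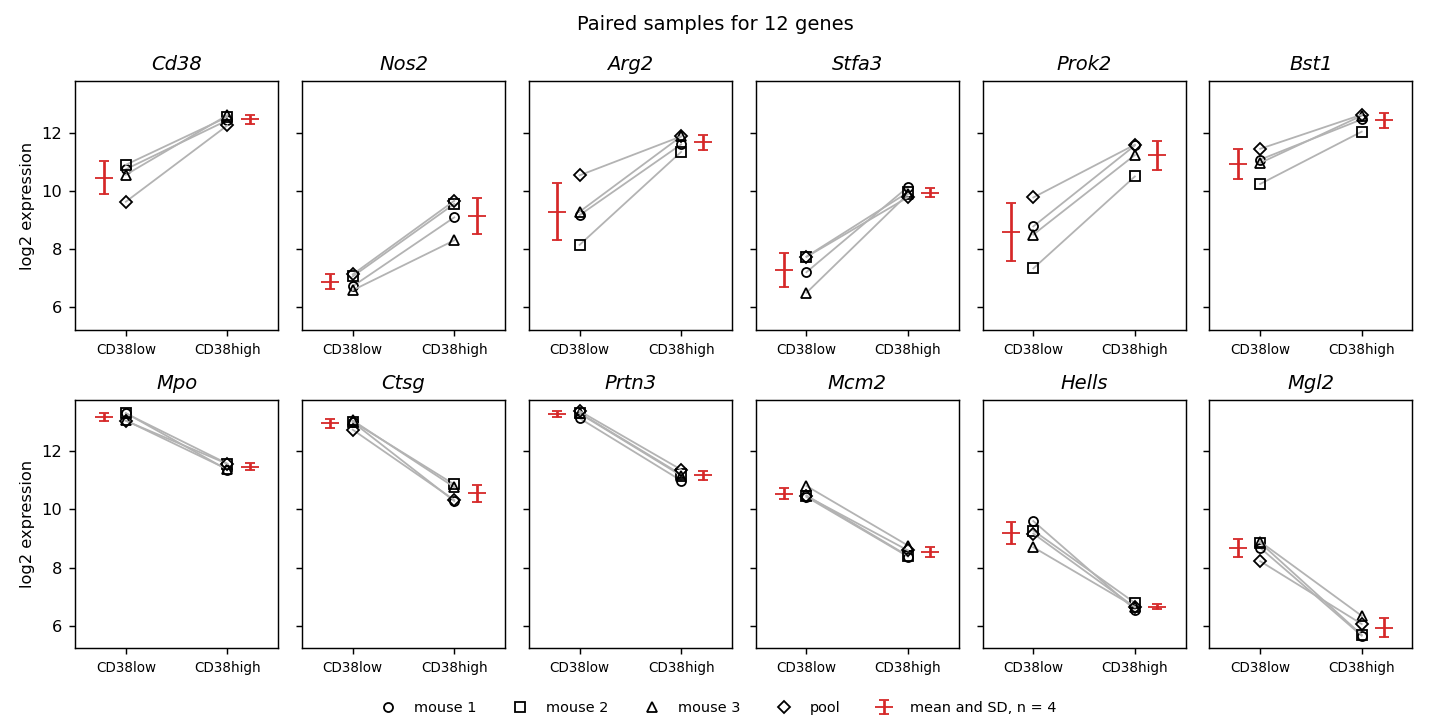
Log2 expression (vertical axis) of 12 genes in the CD38low and CD38high fractions, with a symbol for each mouse or the pool, a line for each pair and a red mark for the mean and SD of the 4 arrays. Every line rises for Cd38, Nos2, Arg2, Stfa3, Prok2 and Bst1 and falls for Mpo, Ctsg, Prtn3, Mcm2, Hells and Mgl2.

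Of the 35 genes on the mature neutrophil list, 6 could be named, and 6 of 6 rose: Stfa3, Il1rn, the interleukin 1 receptor antagonist (2.91-fold), Fpr1, a receptor for formylated bacterial peptides (2.28-fold), Slfn1 (2.28-fold), Hdc, histidine decarboxylase (2.20-fold), and Clec4e (2.16-fold). Against the other named genes the list was shifted upwards with the preset correlation (camera adjusted p = 0.000104) and in Fisher's exact test of direction (adjusted p = 0.000864). It did not pass with an estimated correlation (adjusted p = 0.0758). Its members and the genes it was set against were all selected as changed at least 2-fold on these arrays. Of the 482 named genes 362 were lower, so a list of higher genes stands out easily. These p-values describe the selected genes and are no independent support for a shift. On the list of neutrophil primary granule genes, all 5 of the 14 listed genes that could be named fell in CD38high cells: Ctsg, Ms4a3, Prtn3, Mpo, the myeloperoxidase gene (11.47 ± 0.11 against 13.18 ± 0.15, SD, n = 4 each, 3.27-fold lower), and Elane, the neutrophil elastase gene (3.18-fold lower). Their median log2 difference was -2.10. Against the other named genes this list pointed downwards but did not pass in the unpaired fit (camera adjusted p = 0.067, and 0.31 with an estimated correlation). Most of those genes were themselves selected as lower, so this does not show a smaller shift than that of the mature neutrophil genes. With the replicate block the camera adjusted p of the primary granule list was 0.0227 (adjusted p = 0.301 with the block and an estimated correlation). That call was lost without mouse 1, mouse 2 or the pool (camera adjusted p = 0.0648, 0.0931 and 0.111). Without the block the list passed only when mouse 2 was left out (camera adjusted p = 0.0434 among the 4 fits that leave out a mouse or the pool). The B cell gene Cd79a was higher in the same arrays as the mature neutrophil genes, and Nkg7 was lower in the same arrays as the primary granule genes.

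Of the 40 genes on the cell cycle list, 15 could be named, all from the authors' list of changed genes, and 15 of 15 were lower in CD38high cells, with a median log2 difference of -1.51. They included Mcm2 (4.03-fold lower), Mcm6 (3.87-fold) and Mcm3 (3.68-fold), subunits of the replicative helicase, and Cdc6, which loads that helicase (3.60-fold). Against the other named genes the list was shifted downwards with the preset correlation (camera adjusted p = 0.0218). It did not pass with an estimated correlation (adjusted p = 0.357) or in Fisher's exact test of direction (adjusted p = 0.0562). With 362 of the 482 named genes lower, 15 of 15 gives the smallest p that Fisher's exact test can reach downwards. That result therefore decides nothing about the list. All 7 named genes of the 38 for ribosome biogenesis and MYC targets fell, among them Ppat, the first enzyme of purine synthesis (3.30-fold), and the nucleolar proteins Nop56 (2.78-fold), Nop58 (2.73-fold) and Nop16 (2.44-fold). That list did not pass against named genes that were mostly lower themselves (camera adjusted p = 0.124, and adjusted p = 0.31 with an estimated correlation). The histone H1 genes H1f1 and H1f5 were 2.41-fold and 2.26-fold lower, and Myc was 2.01-fold lower.

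**Figure D3:**
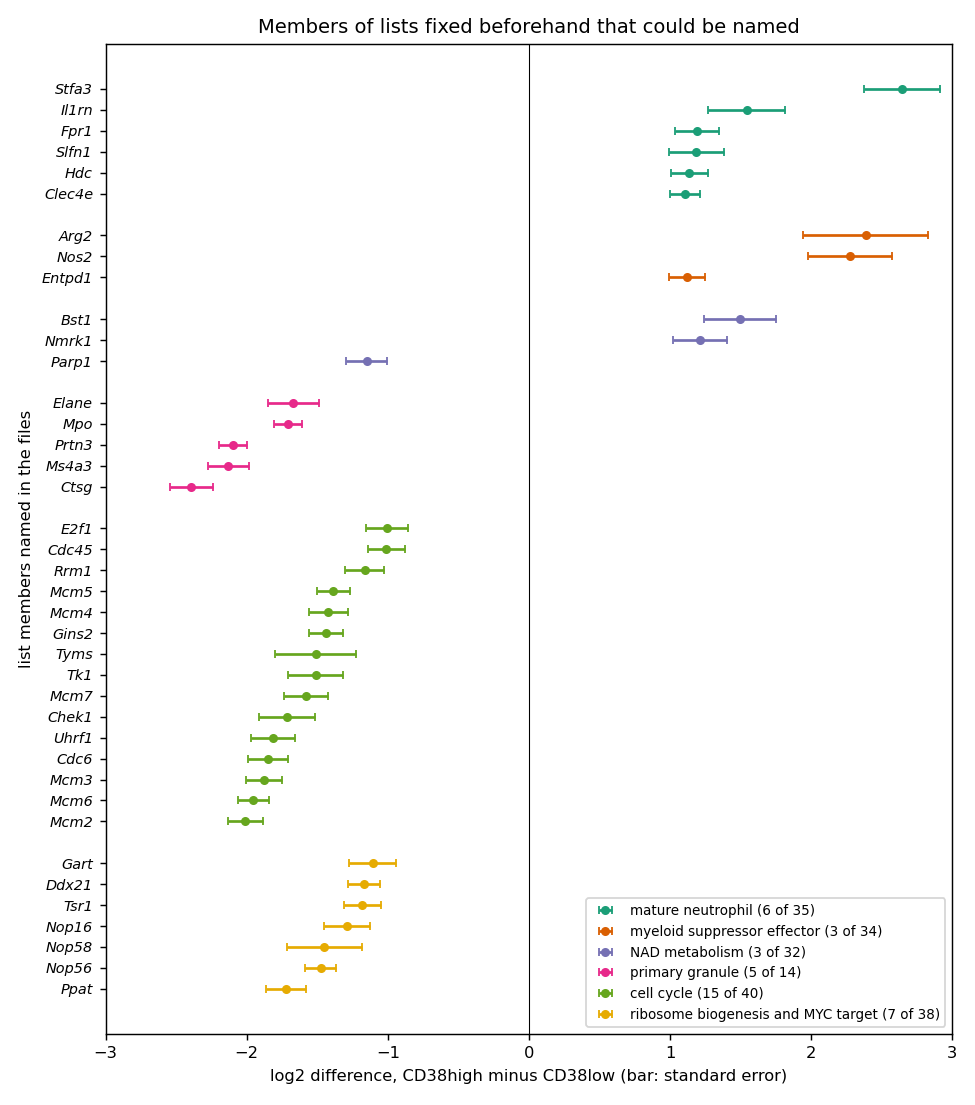
Log2 difference between CD38high and CD38low cells with its standard error (horizontal axis) for each member of 6 gene lists that could be named (vertical axis); the legend gives the named members of each list. The 6 mature neutrophil genes lie above 0 and the 5 primary granule and 15 cell cycle genes below it.

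Of 34 genes linked to suppression by myeloid cells, 3 could be named and all 3 were higher: Arg2, Nos2 and Entpd1, an ectoenzyme that degrades ATP and ADP (2.17-fold, 11.66 ± 0.20 against 10.54 ± 0.17, SD, n = 4 each, limma adjusted p = 0.00218). Nos2 was also the 1 named gene among 40 NF-kB targets. Of 32 genes of NAD metabolism, 2 rose and 1 fell. Bst1, which like CD38 is an ADP-ribosyl cyclase, was 2.82-fold higher and Nmrk1, a kinase for nicotinamide riboside that the files list as BC016495, was 2.32-fold higher. Parp1, a poly(ADP-ribose) polymerase, was 2.22-fold lower. The 2 named genes of the unfolded protein response, Sdf2l1 and Pdia6, were 3.59-fold and 2.45-fold lower. Further lists had 1 named gene each. Adam8 of the secondary and tertiary granule list (2.44-fold), Cd55 of the complement and Fc receptor list (3.53-fold), Ccr7 of the chemokine receptor and T cell lists (2.57-fold), Cd79a of the B cell list, Selp of the platelet list (2.42-fold) and Hdc of the basophil and mast cell list were higher. Nkg7 of the NK cell list, Mt1 of the erythroid list (2.80-fold), Ndufb5 of the oxidative phosphorylation list (2.10-fold) and Myc of the progenitor list were lower. No gene could be named from the lists for monocytes and macrophages (33 genes), the interferon response (49), glycolysis (23), cholesterol synthesis (23), immediate early and stress genes (25), dendritic cells and MHC class II (20), plasma cells (11), eosinophils (14), red pulp and tissue macrophages (20) or stromal and endothelial cells (23). Since names came only from the authors' list of changed genes, each named member passed at an adjusted p of 0.05 over all probesets and adjusted over the list alone, which is not independent evidence of its direction, and an unnamed member is not shown to be unchanged.

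Without both arrays of mouse 1, the unpaired adjusted p rose above 0.05 for 22 of the 52 named genes other than Cd38, among them Arg2 (log2 difference 2.37, limma adjusted p = 0.119), Nos2 (2.24, limma adjusted p = 0.0528), Prok2 (2.57, limma adjusted p = 0.12), Bst1 (1.53, limma adjusted p = 0.0893) and Cd79a (1.89, limma adjusted p = 0.0794). Without mouse 2, mouse 3 or the pool, 2, 11 and 6 of the 52 lost the call. None of the 52 lost it in the paired fit, with all pairs or with any 1 mouse or the pool left out, and none changed sign.

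The authors' deposited table lists 498 probesets, 124 higher and 374 lower in CD38high cells, and all 498 were called in the unpaired and in the paired fit, in the same direction. The series design names a two-sample test at p under 0.001 with a 2-fold minimum and a multivariate permutation test with 10000 permutations. The permutations were not run here, and how they entered the authors' selection and how the variance was estimated are not given in the sources used here. The equal-variance test per probeset alone, called the methods' t-test, gave 351 probesets at that p and fold, and all 351 are in the table. The other 147 had a p of up to 0.00438 in that test. The moderated test of limma at the same settings gave 512 probesets, of which 494 are in the table and 18 are not. At an adjusted p under 0.05 and at least 2-fold, 64 higher and 76 lower probesets lay outside the table and have no gene name here. Of the 64 higher ones, the largest difference was that of probeset 6928716, which was 2.66 ± 0.54 (SE) higher on the log2 scale (limma adjusted p = 0.0203).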

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

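In groups of 4 arrays, an array stood apart where its gap to the nearest of the others, divided by the group's range, was above the critical value of Dixon's test. Of 112 groups tested, over 53 named genes and the array medians, 7 did so, where chance gives about 5.6. In CD38high cells, Cdc6 was at 6.79 in mouse 1 against 7.06 to 7.10 in the other arrays of the group. Entpd1 was at 11.36 in mouse 2 against 11.74 to 11.77 in CD38high cells of the others. Fpr1 was at 13.54 in CD38high cells of mouse 3 against 13.31 to 13.33. In CD38low cells, Igfbp4 was at 10 in mouse 1 against 10.32 to 10.38 and Mcm2 was at 10.81 in mouse 3 against 10.43 to 10.48. The CD38low pool stood apart for Ppat, at 8.71 against 9.06 to 9.11, and for St3gal6, at 8.03 against 6.62 to 6.86. All values are log2 expression, and none of the 7 puts an array among those of the other group.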

How the results depend on the processing

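The restriction to high-numbered probesets, the paired fits with a pair left out, the estimated correlation with the block and Fisher's exact test were chosen after seeing the data. Each of the 53 named genes kept its direction under every alternative run on single genes, and calls were lost only where arrays were left out; the methods' t-test was run on counts alone. The number of differing probesets (2479) rose to 3929 with the replicate block (1626 higher) and to 3840 with a random replicate block (1514 higher). Neither block ended a call of a named gene, and with the fixed block 3 gene lists passed, 2 of them also without mouse 1, mouse 2 or the pool, and 0 with an estimated correlation. Restricted to high-numbered probesets, the count with the block was 4258 (1753 higher and 2505 lower). Without the pool but with the block, 300 probesets were higher at least 2-fold. The methods' t-test gave 351 probesets at its own threshold (78 higher, 273 lower) and 1598 after Benjamini-Hochberg (545 higher, 1053 lower), a test without moderation of the variance. With only named probesets tested, 484 were called (121 higher, all 121 of them at least 2-fold, and 363 lower), which is all that were tested. Leaving out arrays or pairs gave 540 to 2436 differing probesets, 113 to 953 higher and 427 to 1483 lower, with 58 to 248 higher and 222 to 503 lower at least 2-fold. Of the authors' 498 listed probesets 311 to 498 were called, with the lowest values without mouse 1. Of the 4 gene lists, 2 passed in the main analysis, 0 with an estimated correlation and 1 by Fisher's exact test of direction. Between the 2 camera runs, the setting that changed was the correlation between list members, preset at 0.01. Its estimate was 0.175 for the mature neutrophil, 0.262 for the primary granule and 0.475 for the cell cycle list. For the ribosome biogenesis and MYC target list it was 0.0711. A preset below the estimate gives smaller p-values. With an estimated correlation camera also uses the residual degrees of freedom of the arrays, which are far fewer, and this raises its p-values too. The lost calls can therefore not be credited to the correlation alone. Fisher's exact test uses only the direction of each gene. With 362 of the 482 named genes lower, the lists that were lower throughout had the smallest p it can give downwards. None of these passed after adjustment, so that test could not call them. Scaling, dim-probeset filters, trended eBayes and array weights moved no count by over 1.5 times. The median log2 difference of all probesets was between 0.013 and 0.041 under the 3 scalings. Signal over background was not used here. An alternative for linear values was not run, since the values are logarithmic. Over all 35 splits of the 8 arrays into 4 and 4, the real split gave 2479 calls and the highest other 1. So 1 split, the real one, reached that number, but these splits ignore the pairing of the arrays. All splits but the real one also place both fractions in each group, which can lower their calls. Their counts therefore do not measure how many calls arise by chance. The splits that part all 4 pairs number 8, too few for a share under 0.05. Among these the real one gave 2479 calls and the highest other 0 without the block, and 3929 and 0 with it.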

Other observations

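All tests in this part were chosen after the values had been seen, and genes named here beyond the rule were picked from their values. Single genes picked in this way, which belong to no list fixed beforehand and were not tested as a group, included some that were higher in CD38high cells. They were Entpd3, an ectonucleotidase (log2 difference 1.68, limma adjusted p = 0.000684), the ADP receptors P2ry13 (3.43-fold, limma adjusted p = 0.000684) and P2ry12 (2.51-fold, limma adjusted p = 0.00241), the adenosine receptor Adora3 (2.74-fold, limma adjusted p = 0.0046) and Trpm2, a calcium channel gated by ADP-ribose (4.08-fold, limma adjusted p = 0.00646). Slc7a1, a transporter of arginine and other cationic amino acids, was 2.03-fold lower (limma adjusted p = 0.0016) in the same cells in which Arg2 and Nos2 were higher. The G1 and S cyclins and kinases Ccne2, Ccne1, Cdk6 and Cdk4 were 3.53-fold, 3.19-fold, 3.69-fold and 3.12-fold lower. Septin11, which the authors' deposited table lists under a calendar date in place of its symbol, was 2.64-fold lower.

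For the 4 tested gene lists the mean difference had the same direction in each pair, which the choice of their named members from genes changed at least 2-fold on these arrays largely fixes. The mean log2 difference of the 5 primary granule genes was -2.22, -1.93, -1.96 and -1.88 in mice 1, 2 and 3 and the pool, and that of the 15 cell cycle genes was -1.78, -1.67, -1.43 and -1.33. The 6 mature neutrophil genes were at 1.59, 1.36, 1.77 and 1.16, and the 7 ribosome biogenesis and MYC target genes at -1.45, -1.29, -1.36 and -1.27. With 4 pairs, no relation between the lists was tested. Grouped by the letters that open their symbols, 9 families had at least 4 named genes. The Mcm (7 genes), Nup (6), Nop (4) and Rad (4) families were lower throughout (Fisher's exact test of direction, adjusted p = 0.903 each). With 362 of the 482 named genes lower, families of these sizes cannot pass this test downwards. It therefore decides nothing about them. The Cd group, formed by symbol alone, was higher in 5 of 5 (Fisher's exact test, adjusted p = 0.00808). It includes Cd38, on whose protein the cells were sorted. The test also takes genes from the same arrays as independent, so its p-value shows no property of a gene family.

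The cell cycle genes that could be named were mostly genes of S phase. Of 43 widely used S-phase marker genes, 30 were in the authors' deposited table and 30 of 30 were lower in CD38high cells, by between 1.01 and 2.53 on the log2 scale in size, while 0 of 54 G2/M marker genes were in it. The test of that difference (Fisher's exact test, two-sided, p = 3.68e-15) restates what prompted it and describes only the authors' listing, so it decides nothing about the cells. A lower share of cycling cells in the CD38high fraction would lower both sets. Whether it is the whole cause cannot be told apart here from a change confined to S phase. The reason is that the 54 G2/M marker genes could not be located by name. These markers may be missing from the annotation, be more variable between mice, or differ by less than 2-fold. Named genes outside both marker lists were not assigned to a phase, so their values were not used for this question. A candidate explanation for the S-phase set is a difference in maturation between the fractions, with the primary granule genes lower and mature neutrophil genes higher, which was not tested.

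Cd79a and the immunoglobulin lambda constant gene Iglc2 were both higher in CD38high cells, Iglc2 by 4.58-fold (8.69 ± 0.17 against 6.49 ± 0.09, SD, n = 4 each). A single source of B cells in the CD38high sort, with a fixed ratio of both transcripts, would keep the ratio of their excess over CD38low cells near 1 value. The log2 ratio of the excess signals was 1.05, -0.67, 0.60 and 0.07 in mice 1, 2 and 3 and the pool, an SD of 0.737. Since the measurement noise of this ratio is not known from 1 array per fraction and pair, this spread does not decide. B cells with a fixed or a varying ratio, or expression of either gene in the myeloid cells, stay open, and the other 19 B cell markers on the list could not be located by name. The cells were sorted for CD11b and Gr1, but how far this removed B cells could not be examined here.

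The 6577 probesets with numbers below 6000000, of which 14 are in the authors' table, behaved differently from the other 16755. Their median ran from 6.24 in the CD38low array of mouse 3 to 7.23 in the CD38high array of mouse 2, while that of the others stayed between 7.05 and 7.22. The arrays of a mouse or pool lay 0.131 apart on average against 0.329 over all 24 pairings (exact permutation test, one-sided, p = 0.0417, the smallest these pairings can give), which is consistent with a signal carried by the mouse or its processing, and these cannot be separated here. The groups differed by 0.098 (6.85 ± 0.29 in CD38high, 6.76 ± 0.36 in CD38low, SD, n = 4 each; exact permutation test over 70 labelings, two-sided, p = 0.657), less than the SD within either. Of the 2479 calls, 187 were among the low-numbered probesets. The other probesets tested alone gave 3046 calls, so most calls do not depend on testing the low-numbered ones. Testing fewer probesets also changes the adjustment of the p-values. The CD38low array of mouse 3 had the lowest median of the low-numbered probesets and the highest of the others (7.22). An effect of the shift on the values of the other probesets is therefore not excluded. What the low-numbered probesets measure is not given in the sources used here.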
